A study of Arabidopsis thaliana with 2 samples.

How the data were processed

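Expression was measured on 2 Affymetrix arrays of Arabidopsis thaliana accession Columbia-0, 1 hybridised with RNA from the sap of leaf trichomes (the single-celled hairs of the leaf epidermis) and 1 with RNA from the sap of pavement cells (the ordinary ground cells of the epidermis). Per the labels' protocols, sap was drawn from cells of 5-week-old plants with microcapillaries, total RNA was extracted with a micro-scale kit, amplified in 1 round, and labelled with biotin by in vitro transcription. Both arrays are numbered replicate 1, so each group holds 1 array and there is no replicate error for any value.

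The deposited values are log2 signals per probe set, made by the authors with RMA, per the submitters' processing notes; the RMA version, the arrays normalized together and the log base are not given in the sources used here. The log2 scale was taken from the range of the values, 1.28 to 14.2. RMA in its usual form corrects the background, normalizes probe intensities between arrays by their ranks and summarises the probes of each set; which of these steps were run is not recorded, and the values carry no detection call. The columns do not share a single distribution: their sorted values differ by up to 3.99. A set of 703 distinct values occurs on both arrays, and the most frequent value was repeated 90 times on the pavement array and 49 times on the trichome array. Amplification and labelling start at the 3′ end of transcripts, so probe sets far from that end can miss a transcript that is present.

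Of 22810 probe sets, 13513 were paired with exactly 1 gene by the platform annotation of 2016, 503 with several genes, and 8794, which include the array's control probe sets, were not listed there. Names were updated through gene identifiers in the RefSeq table of assembly TAIR10.1, in which 13436 of the probe sets with 1 gene were matched; 77 kept the annotation's name. No coordinates are given, since the build behind the probe annotation was not stated. Probe sets of the same gene were averaged, which gave 13356 genes, 146 of them with more than 1 probe set. The AFFX control probe sets were used as described below.

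The measure was the difference of the log2 signal, trichome minus pavement, with no further scaling. A gene was counted when the difference was at least 1 (2-fold) and its higher value was at or above 2.05, the median of all values. No p-value was computed, because each group has 1 array. The spread between probe sets of the same gene was used as the only available measure of technical error: the pooled SD of the difference was 0.52 over 146 genes, and 0.95 over the 36 genes with a probe set above background. It leaves out the spread due to sampling, amplification and plants. It is also widened where only 1 probe set of a gene gave signal, as for AT1G79150 (differences of 3.66 and 0.18). A background ceiling, chosen after the data were examined, was set at 2.58, the highest reading among 27 probe sets for Bacillus subtilis transcripts. It came from 1 probe set with the same value on both arrays, and the next highest reading was 2.21. A signal at or under this ceiling was treated as a bound: the fold of the brighter over the dimmer array was then computed against the ceiling and is written "at least". Counts and list medians were also computed with such readings raised to the ceiling. Folds apply to the values as deposited. The 18 probe sets for the hybridisation controls (BioB, BioC, BioDn and Cre, bacterial and phage transcripts of known amount that the usual array procedure adds to the labelled sample before hybridisation; the amounts used here are not given in the sources used here) were used to describe the scale between the arrays.

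A set of 25 gene lists with 415 members was fixed before the data were examined. Of these members, 52 (12.5%) had a named probe set, and 29 of those were above the background ceiling on at least 1 array. The median difference of each list with at least 3 measured members was placed among 10000 random lists of the same size, matched on mean level in 20 bins of equal number. This percentile describes these 2 arrays and is not a test of the cell types. Added after the data were examined were lists of plastid-encoded genes, mitochondrion-encoded genes, extensins and leucine-rich repeat extensins, and matching of each member to its 100 or 20 nearest genes in mean level. The genes named in the report were chosen by a rule fixed in advance, and those named in the closing observations from the added lists or as single genes were chosen after their values were seen. The rule took the 15 largest differences each way among genes at or above the floor, and within lists up to 4 members on the side of the median and 2 on the other, with each trichome regulator at or above the floor. Counts and list percentiles were tested on simulated data of 13356 genes in which 200 were changed by a log2 shift of 2 with noise of SD 0.2 per array; 99% of the raised and 100% of the lowered genes were counted in the right direction, with 6 unchanged genes counted, at a noise well under the measured spread between probe sets. With the difference given the measured SD of 0.52, 98% of the changed genes were recovered each way and 623 of 13156 unchanged genes were counted. With the SD of 0.95 over the 2624 genes above background, 87% and 82% were recovered and 666 of 2424 unchanged genes were counted. Of 100 unchanged simulated lists, 7% fell outside percentiles 2.5 to 97.5 with matching in bins and 2% with matching to the nearest genes. Alternatives were the scaling (array medians, reference genes, a lowess trend with a span of 0.3, and, added later, the hybridisation controls), the probe sets used, the floor, the fold threshold and the matching. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6; figures were drawn with matplotlib 3.10.9.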

Results

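The data comprise 1 array of trichome sap and 1 array of pavement cell sap from leaves of 5-week-old Arabidopsis plants, each with 22810 probe sets. The design asks how the transcripts of these neighbouring epidermal cell types differ. Most probe sets read at background on both arrays, with medians of 2.06 (trichome) and 2.03 (pavement) on the log2 scale. Signals above the background ceiling of 2.58 were given by 3169 probe sets (13.9%) on the trichome array and 4218 (18.5%) on the pavement array, and signals above 8 by 20 and 208 probe sets. These counts include the 18 hybridisation control probe sets, with medians of 8.50 in trichome and 11.7 in pavement. Fewer plant probe sets were thus that bright, above all on the trichome array. Across probe sets the arrays correlated with Pearson's r = 0.73 and Spearman's rho = 0.61; probe sets are not independent replicates. With 1 array per cell type, no difference given here has a replicate check, and the number of arrays limits the precision of every value.

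The array controls were examined first, because they set the scale on which the cell types can be compared. The 18 hybridisation control probe sets, for transcripts that the usual procedure adds to each hybridisation, in amounts not given here, all read lower on the trichome array, by a median of 3.15 on the log2 scale (8.87-fold), with differences from -3.54 to -1.94. The 27 Bacillus control probe sets read between 1.52 and 2.58 on both arrays, with a median difference of 0.07. Among the plant controls, the 25S rRNA probe set read 7.13 in trichome and 11.2 in pavement. The 3′ probe set for ubiquitin read 7.37 and 11.2, that for GAPDH 5.60 and 7.01, and that for actin 3.08 and 5.09. A further 3′ probe set for GAPDH was at background (2.33 and 2.16). Of the 5′ probe sets, those for GAPDH (2.17 and 2.03) and actin (2.13 and 2.25) were at background on both arrays, and those for ubiquitin read 2.35 and 5.40 in trichome and 4.07 and 6.68 in pavement.

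**Figure D1:**
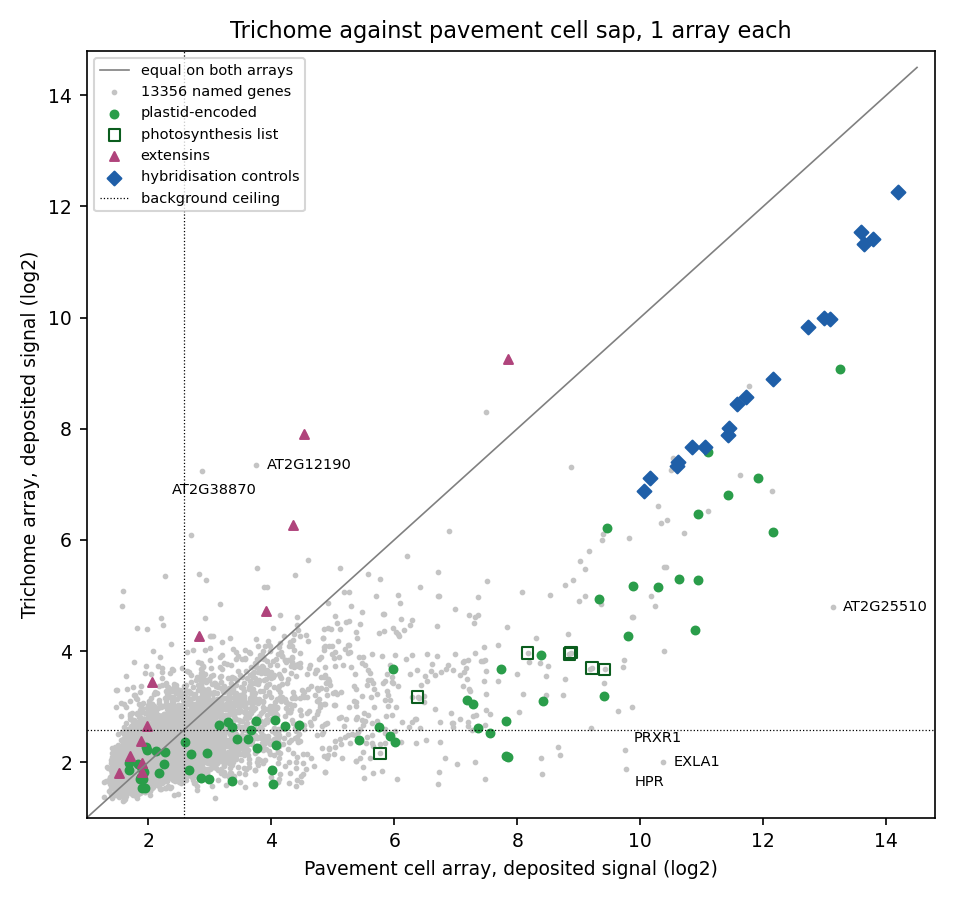
Deposited log2 signal of each named gene on the trichome array (vertical axis) against the pavement cell array (horizontal axis), with hybridisation controls, plastid-encoded genes, the photosynthesis list and extensins marked, the line of equal signal and the background ceiling of 2.58 dotted. The hybridisation controls lie 1.94 to 3.54 below the line of equal signal, and most bright plant genes lie lower still, while AT2G38870, AT2G12190 and several extensins lie above the line.

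More genes read higher in pavement cells than in trichomes. Of the 8168 genes at or above the floor, 679 were 2-fold or more higher in pavement and 97 were 2-fold or more higher in trichome, so that 12.5% of the genes counted were higher in trichome. With readings at or under the background ceiling raised to it, which turns differences against background into bounds, 542 and 43 genes passed 2-fold. In a simulation of genes above background with the spread measured between probe sets, 666 of 2424 unchanged genes passed 2-fold in either direction. A single 2-fold difference is thus not set apart from that spread. The spread came from 36 genes, some with signal on only 1 probe set, so it is a rough guide to error. The split between the cell types depended on the scaling. After a lowess correction of the difference for mean level the counts were 326 and 264, with 44.7% higher in trichome. Of the 1139 genes above the background ceiling on both arrays, 353 were higher in pavement and 23 in trichome as deposited, and 67 and 944 when differences were centred on the hybridisation controls. That centring added 3.15 to every difference, so a gene with equal deposited signals counted as higher in trichome. The controls read 6.88 or more on both arrays, brighter than most of these genes. The shift was not measured at the level of those dimmer genes, so the count of 944 does not show their direction. The difference also grew with level up to a mean of about 6 and no further: the median was 0.01 over the 6253 genes with a mean level from 2 to 3, -1.59 over 209 genes from 4 to 5, -4.59 over 31 genes from 6 to 7, -4.61 over 24 genes from 7 to 8 and -4.31 over 20 genes from 8 to 12.

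Among the named genes, those highest in trichome relative to pavement included a protease inhibitor, a cytochrome P450, an extensin and a lipid transfer protein. Some probe sets without a gene name differed more. AT2G38870, a serine protease inhibitor of the potato inhibitor I type, read 7.23 in trichome and 2.87 in pavement, a difference of 4.36 (20.6-fold). The cytochrome P450 gene AT2G12190 read 7.35 and 3.76, a difference of 3.59. AT1G06320 read 6.08 and 2.69 (10.5-fold). The extensin AT4G08410, a hydroxyproline-rich structural protein of the cell wall, read 7.90 and 4.54 (10.2-fold), from a probe set that can share probes with related genes. The lipid transfer protein gene AT3G58550 read 5.39 and 2.83 (5.88-fold), and AT1G76940 read 5.27 and 2.94 (5.05-fold). With the lowess correction the differences were wider, at 6.64 for AT2G38870, 6.29 for AT2G12190, 5.04 for AT1G06320 and 6.58 for AT4G08410. Relative to the hybridisation controls they were 7.51, 6.74, 6.54 and 6.51. Any gene higher in trichome at these mean levels is widened by either step, so the wider values add no support. The controls read 6.88 or more on both arrays, and their shift was not measured at the pavement levels of these genes.

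The other genes among the 15 were at background in pavement, so that their folds are lower limits. AT1G63730, of the TIR-NBS-LRR class of disease resistance genes, was at least 6.85-fold higher in trichome, and AT5G43150 at least 5.64-fold. AT3G33066 was at least 4.71-fold higher, AT3G19660 at least 4.03-fold and AT4G17215 at least 3.71-fold. The value for AT3G33066 came from a probe set of a type that can share probes with other transcripts. The F-box gene AT2G36090 was at least 3.54-fold higher, AT1G80170 of the pectin lyase-like family at least 3.53-fold, and AT5G40070 at least 2.32-fold. For AT1G79150, at least 2.68-fold higher as a mean, the probe sets had differences of 3.66 and 0.18. The second was at background on both arrays (2.19 in trichome and 2.01 in pavement), so the difference rests on 1 probe set.

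Among the named genes, those highest in pavement relative to trichome included EXLA1, AT2G25510, HPR and PRXR1. EXLA1, an expansin-like protein of the cell wall, read 10.4 in pavement and 2.01 in trichome, at least 221-fold higher in pavement. AT2G25510 read 13.1 and 4.80 (321-fold), and its difference of -8.33 was -3.00 with the lowess correction for mean level. That correction was larger than the median shift of -4.31 over the 20 genes with a mean level from 8 to 12, so -3.00 understates its distance from them. HPR, the hydroxypyruvate reductase of photorespiration, read 9.77 and 1.88 (at least 146-fold), and the peroxidase PRXR1 read 9.76 and 2.22 (at least 145-fold). Relative to the hybridisation controls AT2G25510 was still lower in trichome, with a difference of -5.18. EXLA1, HPR and PRXR1 were at background in trichome, and their differences from the controls were at most -4.64, -4.04 and -4.03.

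The other 11 genes higher in pavement by this rule included 3 genes of the plastid genome. AT5G38980 was 117-fold higher in pavement, the dioxygenase gene AT2G25450 105-fold, and AT4G23670, of the major latex protein family, 95.3-fold. AT5G40450 was 82.9-fold higher, with a difference of -6.37 that was -2.41 after the lowess correction. The plastid genes psbZ, petB and psaB, which encode parts of photosystem II, the cytochrome b6f complex and photosystem I, were 92.1-fold, 74.7-fold and 64.6-fold higher. With the lowess correction for mean level their differences were -2.22, -2.94 and -0.55. For psaB the correction was larger than the shift of genes of like level. Its deposited difference was -6.01, and the 100 genes nearest to it in mean level had a median of -4.30. Of those 100 genes, 10 had a lower difference than psaB. Most of the 100 were dimmer than psaB, since only 20 genes had a mean level from 8 to 12. The median of these 20 was -4.31. Genes at background in trichome were ECS1 (at least 69.0-fold), AT1G55960 (at least 67.8-fold), AT5G14120 (at least 56.5-fold) and the leucine-rich repeat kinase gene AT1G07650 (at least 55.8-fold). Relative to the hybridisation controls, the 7 of these genes above background on both arrays had differences from -3.73 for AT5G38980 to -2.86 for psaB.

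Photosynthesis genes, listed in advance as markers of mesophyll, were all higher in pavement: 7 of 7 measured members by 2-fold or more, with a median difference of -4.90 (quartiles -5.21 and -3.91). The antenna protein genes LHCB4.1 and LHCB4.2 read 9.42 and 9.21 in pavement and 3.67 and 3.70 in trichome, 53.8-fold and 45.7-fold higher. RCA, which encodes rubisco activase, was 29.9-fold higher, and PSAE-1 of photosystem I 29.9-fold higher. The list median lay at percentile 0.04 of random lists matched in bins of mean level, at percentile 2.31 when each member was matched to its 100 nearest genes and at percentile 8.80 with the 20 nearest. It was -1.75 when centred on the hybridisation controls. Of the 3 photorespiration genes measured, HPR and GLYK (AT1G80380, at least 3.84-fold) were higher in pavement by more than 2-fold, and GLDT (AT1G11860) read 4.44 in pavement and 3.73 in trichome. The list median was that of GLYK, which was at background in trichome, so that only a bound of -1.94 is known for it, and its sign relative to the hybridisation controls is not settled.

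Of the 21 listed regulators of trichome development, 4 had a named probe set, and these were mostly at background on both arrays. The others, among them GL1, GL2, GL3 and TTG1, were not measured. Of the 4 measured members, only SIM, an inhibitor of cell division in trichomes, was above the background ceiling, at 2.79 in trichome and 2.06 in pavement. ATMYC1 was at background on both arrays with a difference of -0.22, and the 2 members under the floor were GIS and TRY. With readings at background raised to the ceiling, the list median was 0. In the list of trichome shape and cytoskeleton genes, 2 of 7 measured members differed by 2-fold or more, both higher in pavement: TBR (AT5G06700), needed for the crystalline cellulose of trichome walls, read 6.83 in pavement and 2.07 in trichome (at least 19.0-fold), and KIC (AT2G46600), a calcium-binding regulator of a kinesin in trichome branching, read 7.47 and 3.47 (16.0-fold). The other 5 members, among them SPK1 (2.43 in pavement and 2.36 in trichome), were at background on both arrays. With readings at background raised to the ceiling, the list median was 0.

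Markers of the other cell types that leaf sap could hold were few among the named probe sets. The stomatal lineage factors MUTE, FAMA (FMA) and SPCH read 2.96, 2.87 and 2.62 in trichome, just above the background ceiling, and were at background in pavement, with differences of 0.90, 0.87 and 0.61. As bounds these were at least 1.29-fold, 1.22-fold and 1.02-fold, so a 2-fold difference was not shown for any of the 3. Their median lay at percentile 99.8 of random lists as deposited and 99.7 with readings at background raised to the ceiling, ranks that rest on pavement readings at background. The deposited medians of the other short lists lay at percentile 59.8 for trichome regulators, 32.7 for trichome shape, 7.09 for flavonoids, 10.1 for photorespiration and 29.7 for reference genes. The vascular sugar transporter gene SWEET11 read 2.08 in trichome and 2.14 in pavement, and ACR4 (CR4), a receptor kinase of the epidermis, 2.08 and 1.68. No member of the list for pavement cell lobing had a named probe set.

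In the flavonoid list, none of 5 measured genes was shown to differ by 2-fold. UGT78D1, a flavonol glycosyltransferase, read 2.88 in pavement and 1.78, at background, in trichome (at least 1.23-fold). UGT78D2 read 3.57 and 2.90, and DFR, an enzyme of anthocyanin synthesis, 1.97 and 2.71. With readings at background raised to the ceiling, the list median was 0. The 4 reference genes measured (PEX4, or UBC21, AT5G25760; AT4G34270; AT2G32170; AT2G28390) had differences from -0.23 to 0.03 with a median of -0.13, and 3 of them were at background on both arrays.

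Lists with 1 or 2 measured members are given by gene. In phenylpropanoid synthesis, ALDH2C4 (REF1) read 6.51 in pavement and 2.40 in trichome (at least 15.3-fold), and HCT 3.24 and 2.42. The rapid stress factors WRKY53 and STZ (ZAT10) read 4.93 and 4.44 in pavement and 2.13 and 2.51 in trichome, at least 5.09-fold and 3.63-fold higher in pavement. In wax and lipid synthesis, FATB, a fatty acyl thioesterase, read 5.07 and 3.22 (3.61-fold), and WSD1 was at background. The glucosinolate glucosyltransferase genes UGT74C1 (AT2G31790) and UGT74B1 read 3.34 and 3.23 in pavement and 2.05 and 2.47 in trichome, and BCAT4 was at background. The clock gene GI read 3.08 in pavement and 1.36 in trichome. COB, a protein of cellulose deposition, read 3.05 and 2.90. EXPA8 of the wall loosening list, THI2.1 and PDF1.2 of the jasmonate list, ATHSP22.0 of the heat shock list, and SIR and MT1C of the sulfur list were at background on both arrays. The lists for the endocycle, myrosinases, pavement cell lobing, pathogen defence and aquaporins had no named probe set.

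**Figure D2:**
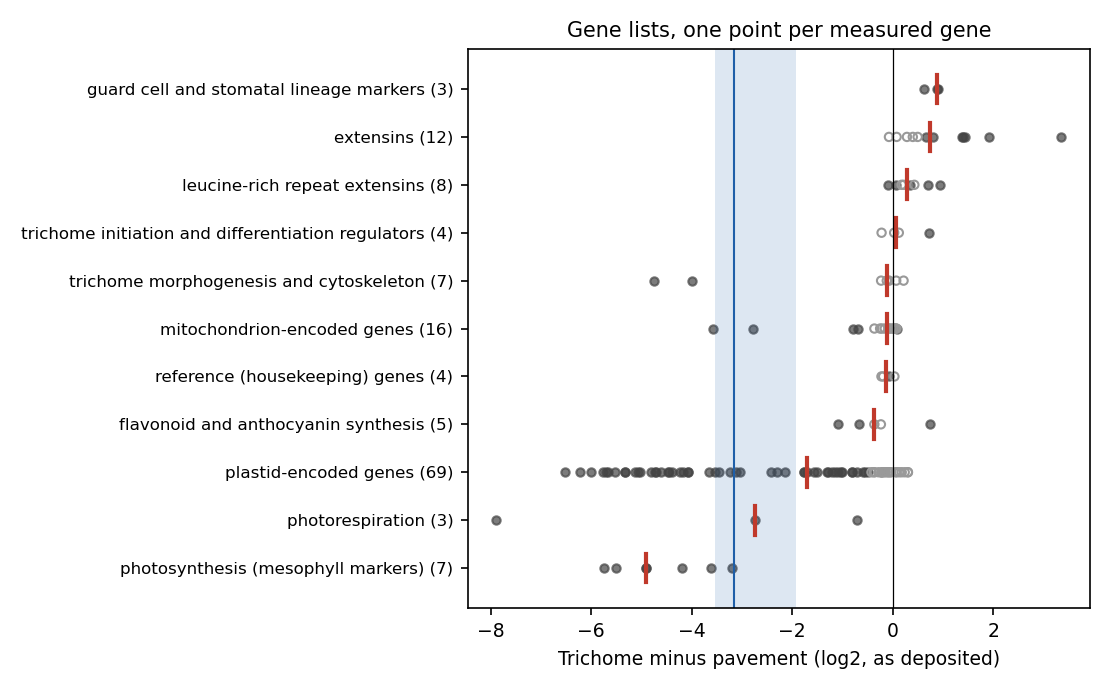
Difference of the log2 signal, trichome minus pavement, for each measured gene (points) of the lists with at least 3 measured members, the number of which is given in brackets. Filled points were above the background ceiling on at least 1 array, open points on neither, red bars are list medians as deposited, and the blue line and band are the median and range of the hybridisation controls (-3.15, from -3.54 to -1.94); the 7 photosynthesis genes lie between -5.75 and -3.21.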

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

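The tests on the hybridisation controls, the nearest-level matching, the photosynthesis level in pavement and the unnamed probe sets were chosen after the results were seen.

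Signal outside the gene comparison drew attention in both the controls and the probe sets without a gene name. The hybridisation controls differed by a median of -3.15 between the arrays (trichome minus pavement). Of 8730 plant probe sets with no gene listed, 70 were above the background ceiling and 2-fold or more higher in trichome, and 710 were so in pavement; with readings at background raised to the ceiling these counts were 33 and 588. The widest of these differences were those of a probe set that read 8.90 in trichome and 3.17 in pavement and of another that read 11.4 in pavement and 1.67, at background, in trichome.

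The first pattern is that 679 genes were 2-fold or more higher in pavement and 97 in trichome. A difference in brightness or scaling between the arrays is consistent with the control median of -3.15, although less of the controls added to the trichome sample would give the same value. A lower yield of plant RNA from trichomes as the whole cause cannot be told apart: 18 of 18 control probe sets were lower on the trichome array, which equal amounts of controls would speak against, but the amounts are not recorded. Plant genes gave no single shift across all levels: the median was -0.37 over the 1139 genes above background on both arrays. By mean level it was -1.59 over 209 genes from 4 to 5, -3.12 over 94 genes from 5 to 6 and -4.59 over 31 genes from 6 to 7. Above that it fell little further, at -4.61 over 24 genes from 7 to 8 and -4.31 over 20 genes from 8 to 12. The controls read 6.88 or more on both arrays, so the brightest bands are nearest to their level. The medians of these bands lay below the control median of -3.15. With the amounts of the controls not recorded, this gap does not settle the cause. A real difference in transcript content between the cell types stays open, as untested.

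The second pattern is the low signal of photosynthesis genes in trichome. A loss shared by all bright plant genes cannot be told apart from a specific one for the 7 listed genes, because their median lay at percentile 8.80 of random lists matched to the nearest 20 genes and at percentile 2.31 with the nearest 100. Mesophyll RNA or chloroplasts drawn into the pavement capillaries could also raise them. Their median level of 8.85 on the pavement array, with LHCB4.1 the brightest at 9.42, is what carry-over and expression of these nuclear genes in the pavement cells themselves both predict, and how many of the 7 the epidermis itself expresses was not measured here, so this cannot be told apart. A difference in plastid content between trichomes and pavement cells is the biological explanation that the groups give, and was not tested.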

How the results depend on the processing

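No paired analysis was possible because each cell type has 1 array, and for the same reason no replicate could be left out. Of the alternatives below, the background ceiling, the hybridisation controls and the nearest-level matching were chosen after the data were seen. The counts of 97 genes higher in trichome and 679 higher in pavement were 92 and 672 with _at probe sets alone and 98 and 681 with the brightest probe set per gene. Removing the floor could not change them, since the lowest value was 1.28, and other floors hardly could. Centring on array medians or on reference genes (139 and 586) rests on probe sets mostly at background and says little about bright genes. The counts were 264 and 326 with the lowess correction, 14 and 303 at a log2 difference of 2, 43 and 542 with readings at background raised to the ceiling, 23 and 353 for genes above background on both arrays, and 944 and 67 when those were also centred on the hybridisation controls. The controls were brighter than most of those genes, so the count of 944 applies a shift not measured at their level. Centring on the controls adds 3.15 to every difference alike, so what it turns follows from its size. It gave list medians of 3.22 (trichome regulators), 4.02 (stomatal lineage) and -1.75 (photosynthesis). The sign was turned for trichome shape (3.03), flavonoids (2.78), reference genes (3.02), photorespiration (0.41), plastid-encoded genes (1.44) and mitochondrion-encoded genes (3.03). Except for photosynthesis, these medians rest on readings at background on 1 or both arrays, where the shift has no clear meaning. The photosynthesis median was -1.54 after the lowess correction. The trichome shape median was -4.00 over the 3 members with a mean at or above the floor (KIC, TBR and SPK1, the last at background). Percentiles crossed the 2.5th with unmatched random lists for flavonoids (from 7.09 to 2.1) and photorespiration (from 10.1 to 0.05), and with matching to the nearest 20 genes for photosynthesis (8.80); the causes were not tested. The named genes were chosen for their size, so that keeping their sign under these shifts is no test of them. Signals near 2 cannot show whether a transcript was present, which limits most genes on both arrays.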

Other observations

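The lists, tests and single genes in this part, all of them, were chosen after the data were seen. Of 69 measured plastid-encoded genes, 40 were 2-fold or more higher in pavement, and none was so in trichome. Readings at background were raised to the ceiling for these counts, so that differences against them are bounds. The median difference was -1.43 with such bounds and -1.71 as deposited, and in both cases none of 10000 random lists matched to the nearest 100 genes in mean level had a median as low. As deposited it was -0.59 with the lowess correction and -3.08 over members with a mean at or above the floor. With bounds, genes of the ATP synthase had a median of -4.57 (5 of 6 past 2-fold), those of photosystem I -3.34 (4 of 5), of photosystem II -1.43 (8 of 15), of plastid ribosomal proteins -1.49 (9 of 15), of the NDH complex -1.15 (5 of 10), of the RNA polymerase -0.30 (1 of 4) and of the cytochrome b6f complex 0 (2 of 6). These medians depend on which probe sets gave signal and do not rank the complexes. Within photosystem I, psaB read 12.2 in pavement and psaA 1.88. Within the cytochrome b6f complex, petB read 9.41 there and petD 1.91. The brightest, atpE, read 13.2 in pavement and 9.07 in trichome, and 53 of the 100 genes nearest to it in mean level had a lower difference. Most of these 100 were much dimmer than atpE, since only 20 genes had a mean level from 8 to 12. Centred on the hybridisation controls, the deposited median of all 69 became 1.44, but it is that of psbT, at background in trichome, so its sign on that scale is not settled. Of 16 mitochondrion-encoded genes, nad4 (7.41 in pavement and 3.83 in trichome) and cox1 (5.52 and 2.74) were 2-fold or more higher in pavement; the list median was -0.12 as deposited and 0 with bounds.

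Among single genes, the dehydrin-related genes COR47 (10.4 in pavement and 6.35 in trichome) and AT1G54410 (11.8 and 8.77) and the cytosolic isocitrate dehydrogenase gene cICDH (9.74 and 3.84) were bright in pavement, with differences of -4.08, -3.00 and -5.90. The hybridisation controls had a median of -3.15, so AT1G54410 was not lower in trichome relative to them. Neither COR47 nor AT1G54410 went beyond the median of -4.31 over the 20 genes with a mean level from 8 to 12. On the trichome side, the extensin genes AT1G23720 (9.26 in trichome and 7.85 in pavement), HRGP1 (6.27 and 4.35) and AT5G19810 (4.27 and 2.83) were above background on both arrays.

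The third pattern is that extensin genes above background read higher in trichome: 11 of 12 did, with readings at background raised to the ceiling. These 12 include the 5 members noticed first. Above background on both arrays were 5 extensins and 3 leucine-rich repeat extensins. AT3G54580, AT5G26080 and PEX2 (AT1G49490) passed on the trichome array alone and PEX3 (AT2G15880) on the pavement array alone, which fixed their signs. The other 8 of 20 measured members were at background on both arrays. Past 2-fold were 4 extensins, 3 of them read by shared probe sets, and no leucine-rich repeat extensin. The deposited list medians were 0.74 over 12 extensins (0.44 with bounds and 0.45 with _at probe sets alone) and 0.28 over 8 leucine-rich repeat extensins (0.03 with bounds). Without the 5 members noticed first, 7 members were above background, with a median with bounds of 0.20 (percentile 99.4 of random lists of such genes of like level). However, 2 of them passed on the trichome array alone, which fixed their sign. The 4 above background on both arrays had differences from 0.06 to 0.95 and a median of 0.57 (percentile 99.5). They were LRX4, LRX5, AT4G33970 and AT5G06630, the last read by a shared probe set. Their matched random lists had a median of -0.62. None of the 4 exceeded the SD of 0.95 between probe sets of the same gene. A shift shared by the family would give this rank, but values within that SD cannot show it. Cross-hybridisation among repetitive proline-rich sequences cannot be told apart from expression. The 4 probe sets marked as shared had the differences 0.81 to 3.36. The 8 unique probe sets above background had a median of 0.27 with bounds, 7 of them positive and the highest at 1.44, with no replicate array to check them. Only 4 of these 8 were above background on both arrays, and the array on which the others passed fixed their signs.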
